A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

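Targeted RNA sequencing was analysed in 12 samples from HEK 293T and 46C mouse embryonic stem cells transfected with fragment libraries in reporter constructs. Per the labels' protocols, cells were harvested 24 hours after plating, RNA was reverse-transcribed with a primer downstream of the insertion site, and the product was amplified by PCR before library preparation. The submitters' processing notes name CASAVA, Bowtie 1.0.0, TopHat2 2.0.11, bedtools and the mouse build mm9, with no role or order. Read trimming, filters and the handling of reads that match several places are not given in the sources used here.

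The authors deposited 3 tables. In the RTM and Xist tables, per the file headers, each value is the authors' ratio of cytoplasm to chromatin read density in a 10-nt bin of a strand, given to 2 decimals (8706 RTM and 3122 Xist bins). Read counts and densities are not in these tables, so the depth behind a ratio is unknown and no counting interval is given. Bins with no value were left out. The Xist table also holds the authors' mean ratio over libraries, and both tables hold the authors' p-values per bin from a t-test, whose form is not given in the sources used here. The authors' mean over all reporters in the Xist table matches the mean of 4 libraries, without GFP-Xist-293T, within 0.015. The column 5AI-RTM was taken as the library 5AI-RTM-293T because the other titles with these words have columns of their own. In the NXF1 table, per the file headers, the authors deposited raw read counts per mutation for whole cell, cytoplasm, nucleus and chromatin, with a row of counts for the unmutated fragment (60162, 55229, 82065 and 67663 reads, which is 3.52% to 4.42% of the reads listed). Reads with several mutations may be listed in several rows, which the sources used here do not say.

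For the RTM and Xist tables, log2 chromatin over cytoplasm was computed as minus log2 of the ratio plus a pseudocount of 0.01, averaged in windows of 100 nt that had at least 50% of their bins, and centred on the library median (873 RTM and 312 Xist windows). Bins less than 20 kb apart formed a region, which gave 7 RTM regions and 1 Xist region. At the start of the Xist region both strands hold a run of equal values (149 bins in all), which was kept, and left out as an alternative. Profiles were compared with Pearson's r and Spearman's rho across windows, with two-sided p-values from 10000 circular shifts within each region and strand. Strands were compared at bins listed on both, with two-sided p-values from 10000 random sign flips of 1-kb blocks. That comparison, the count of windows on the same side in every library (1000 rotations), and the strand comparison between cell lines were added after the data were seen. Adjusted p-values are from Benjamini-Hochberg over the family named.

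For NXF1, mutated reads were summed per site, and sites with at least 100 reads in both columns were tested against the unmutated row with Fisher's exact test, with a log2 odds ratio and its 95% Wald interval. Deletions and substitutions were both included. At 5 sites the p-value was below the smallest number that could be computed, so sizes and intervals are given instead. 5′ splice site-like stretches were sites inside GGTAAG, GTAAGT or CAGGTA in the main test. Matches to CAGGTAAGT with at most 2 mismatches and GTAAG were the alternatives. Their p-value is from all 145 circular shifts along the consecutive sites. Because 2 compartments of 1 library are compared, these tests do not compare conditions.

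Groups were taken from the sample titles. Regions were named by a rule fixed before the data were examined, which took the 3 highest and 3 lowest windows of each library (the first of each is given here), windows in the top 5% of every library of an RNA, and the median of every region. For NXF1 it took the 10 sites with the largest absolute log2 odds ratio among those with an adjusted p under 0.05 and every site of a U1 motif. Substitutions toward the consensus and deletions were singled out after their values were seen. The comparison of windows with and without U1 or other motifs in the RTM and Xist regions needs their sequence and was not analysed here. A filter on low densities and centring on library totals need densities and were not run.

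The tests were run on simulated data first. With 30 of 146 NXF1 sites changed by 0.3 on the log2 scale at the real depths, 28 were called, and 29 when changed by 0.6, with 0 of 116 unchanged sites called in both. The unchanged sites were drawn at the unmutated ratio with counting error only. Real sites outside the consensus matches had a median of −0.26 and a robust SD of 0.16. The simulation therefore gives no rate of false calls for them. Of 100 unrelated pairs of rotated Xist profiles, 3 were called at 0.05, and all 100 when shared and own variance were equal. Of 100 simulated Xist strand comparisons without a difference 8 were called, and 91 with a difference of 0.3. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.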

Results

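The series measured where RNA fragments end up in the cell. Libraries of fragments were cloned into reporter constructs, transfected into cells, and read by targeted sequencing of reverse-transcribed reporter RNA 24 hours after plating. There were 12 samples in 11 groups. The HEK 293T line, derived from human embryonic kidney, gave 6 of them, and the mouse embryonic stem cell line 46C gave the other 6. Constructs are labelled GFP, 3AI or 5AI, and fragment libraries RTM, Xist or mNXF1; the sources used here do not spell out AI, RTM or "short". The RTM and Xist values are cytoplasm-over-chromatin read-density ratios without read counts, so their depth is unknown. They are shown turned round, as log2 chromatin over cytoplasm with each library's median set to 0, so that a positive value lies on the chromatin side. Except for the pair labelled 5AI-RTM-short, each group holds 1 library, and no difference between single libraries has a replicate check.

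The NXF1 library asked which bases of a fragment of this RNA, labelled for the mRNA export factor NXF1, set its place in stem cells. The largest drops of mutated reads in chromatin relative to cytoplasm lay in a stretch of the fragment that resembles a 5′ splice site under the wider consensus rule, though not under the list of motifs fixed for the main test. At site 41, in the numbering of the deposited table, mutated reads were 3.69-fold lower in chromatin over cytoplasm than unmutated reads (log2 odds ratio −1.89 ± 0.03, 95% interval half-width). At sites 40, 44 and 43 the log2 odds ratios were −1.85 ± 0.06, −1.68 ± 0.08 and −1.49 ± 0.04. These sites lie in CAGGTGAGT (sites 37 to 45), which has 1 mismatch to CAGGTAAGT, the 5′ splice site consensus that pairs with U1 small nuclear RNA. All 9 of its sites were lower than the unmutated row by Fisher's exact test (two-sided, Benjamini-Hochberg over 146 sites), with a median of −0.90. So were 122 of the 146 sites of the fragment. Sites 37 (−0.23 ± 0.06) and 42 lay above the median of −0.26 of the sites outside the consensus matches. Site 42 stood at −0.15 ± 0.06 with its deletion row and at 0.07 ± 0.07 with substitutions only. Of its substitutions, G42A was higher than the unmutated row (0.15 ± 0.08), and G42T (−0.21 ± 0.16) and G42C (−0.47 ± 0.38) were lower.

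The second 5′ splice site-like stretch, AAGGTAAGG (sites 52 to 60, 2 mismatches), moved the same way in 8 of its 9 sites, with a median of −0.65. Sites 54 and 55 had log2 odds ratios of −0.78 ± 0.06 and −0.82 ± 0.07. Sites 56, 57 and 58 had −0.70 ± 0.04, −0.59 ± 0.03 and −0.66 ± 0.04. Site 59 stood at −0.09 ± 0.03, and at −0.55 ± 0.05 when the deletion row at this run of G was left out. Site 60, where the fragment does not match the consensus, was higher (0.26 ± 0.05, Fisher's exact test, adjusted p = 8.92e-30). The 6 sites inside GGTAAG, GTAAGT or CAGGTA, the list fixed before the data were examined, are sites 54 to 59 of the second stretch. The first stretch holds none of these motifs, and its sites count among the remaining ones. The 6 sites lay below the remaining sites by −0.42 in median (circular-shift permutation p = 0.0414, two-sided, over 145 shifts). With the wider consensus rule of at most 2 mismatches, 18 sites lay below the rest by −0.41 (permutation p = 0.0138). With GTAAG alone the difference was −0.39 (permutation p = 0.0828), and with substitutions only, an alternative added later, −0.41 for the fixed list (permutation p = 0.0552). The smallest p these shifts can give is 0.0069.

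**Figure D1:**
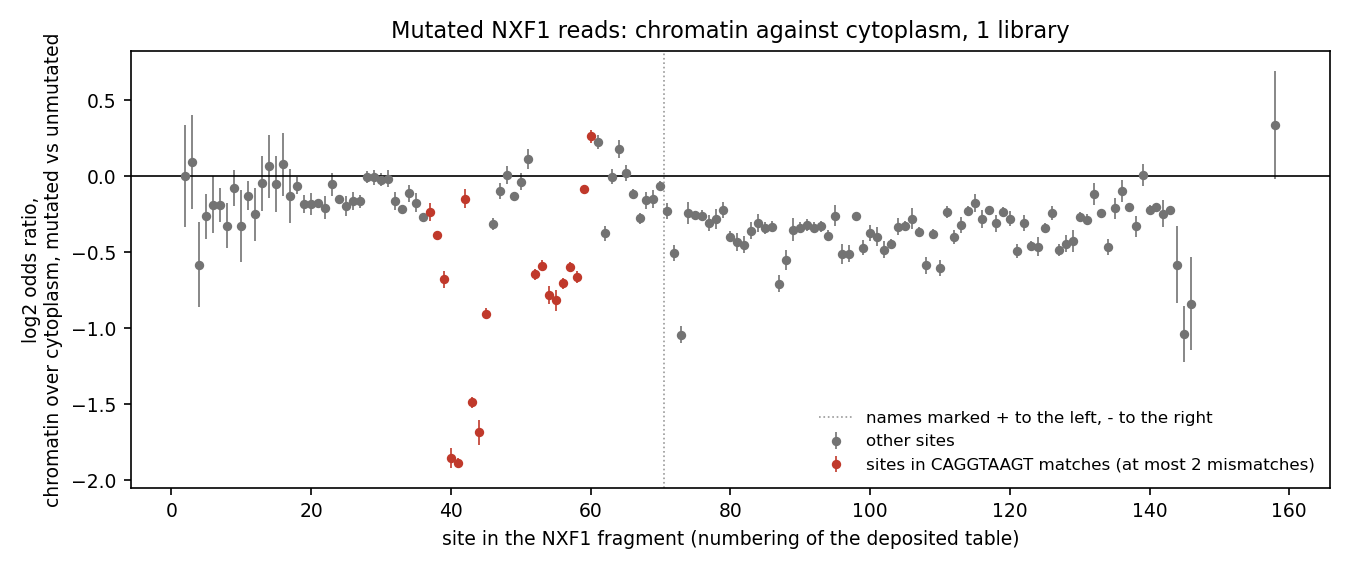
Each point is a site of the NXF1 fragment (x axis, site number); the y axis is the log2 odds ratio of mutated against unmutated reads, chromatin over cytoplasm, with bars for the 95% counting interval. Sites 40 to 45 of the first consensus match (red) reach −1.89, and those of the second match lie between −0.82 and 0.26.

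Single substitutions gave the same picture. G40T had a log2 odds ratio of −2.05 ± 0.21, T41C −2.04 ± 0.04, G44T −2.01 ± 0.17, G40A −1.89 ± 0.07 and A43T −1.86 ± 0.05. Of the substitutions that take away a matched base, 22 of 23 in the first stretch and 21 of 21 in the second were lower, with medians of −1.14 and −0.69. Over the whole fragment 336 of 480 mutations were lower. G42A, which makes the first stretch a full match, was higher in chromatin than the other substitutions of its site by 0.40 ± 0.16 (Fisher's exact test, adjusted p = 2.23e-06), and A52C in the second stretch by 0.59 ± 0.11 (exact test, adjusted p = 1.28e-24). G60T, also toward the consensus, was lower than the others of its site, by −0.21 ± 0.09 (Fisher's exact test, adjusted p = 5.54e-06). Against the unmutated row G42A stood at 0.15 ± 0.08, A52C at −0.15 ± 0.11 and G60T at 0.17 ± 0.07. Deletions of a base were lower at all 7 sites of the first stretch where one was tested, from −1.73 ± 0.19 at site 43 to −0.60 ± 0.18 at site 38. In the second stretch they were lower at 5 of 7, the lowest at site 56 (−0.73 ± 0.16); G54del did not differ (−0.10 ± 0.22) and G59del was higher (0.10 ± 0.03).

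Outside these stretches the largest values were at site 73 (−1.04 ± 0.06, with G73C at −1.73 ± 0.20), site 145 (−1.04 ± 0.18) and site 146 (−0.84 ± 0.30), the last with 146 chromatin reads. Most of the fragment was shifted: 122 sites were lower and 4 higher than the unmutated row, and the 128 sites outside the consensus matches had a median of −0.26. Reads listed at a site may also carry mutations at other sites, which unmutated reads lack. The sources used here do not say how such reads were listed. This general shift can therefore not be assigned to the single sites. The median site lay at −0.27. Set against it in place of the unmutated row, which raises every value by that amount, 59 sites were lower and 53 higher, and site 59 was higher (0.18). These calls are from an exact binomial test that takes the median ratio as known, in place of Fisher's test. A near-even split is built into this reference. Sites 37 (−0.23) and 42 (−0.15) of the first stretch also lay above the median site. For nucleus over cytoplasm the median log2 odds ratio was −0.51 in the first stretch and −0.22 in the second, against −0.18 outside the matches. For chromatin over nucleus it was −0.39 and −0.38, against −0.09. The table lists 497 mutations, whose counts add up to 1422087 in the cell column, 1515205 in cytoplasm, 1931156 in nucleus and 1464343 in chromatin. These tests compare columns of 1 library, and intervals and p-values cover counting error only, since reads are PCR products with no molecular identifier stated in the sources used here.

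The Xist libraries asked which parts of this RNA lie on the chromatin side. Xist, the long noncoding RNA of X inactivation, is transcribed from the minus strand of the mouse X chromosome, and the table lists fragments of both strands. The sources used here do not define the strand further. Minus-strand fragments lay further to the chromatin side than plus-strand fragments in 4 of the 5 libraries. The mean difference, over 157 windows of 100 nt listed on both strands, was 0.97 in 3AI-Xist-46C, 0.45 in 3AI-Xist-293T, 0.36 in 5AI-Xist-293T and 0.24 in GFP-Xist-293T. It was −0.03 in GFP-Xist-46C. Random sign flips of the 19 1-kb blocks (two-sided, Benjamini-Hochberg over 11 libraries) gave adjusted permutation p-values of 0.00055, 0.00055, 0.00522, 0.0022 and 0.73 in that order. Raw values of 0.0001, the smallest these flips can give, stood behind the first pair. Windows and blocks are not replicates of a condition. With the 5 libraries as the unit, the mean was 0.40 ± 0.37 (SD, n = 5) and the exact sign-flip p was 0.125, where the smallest possible is 0.0625.

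**Figure D2:**
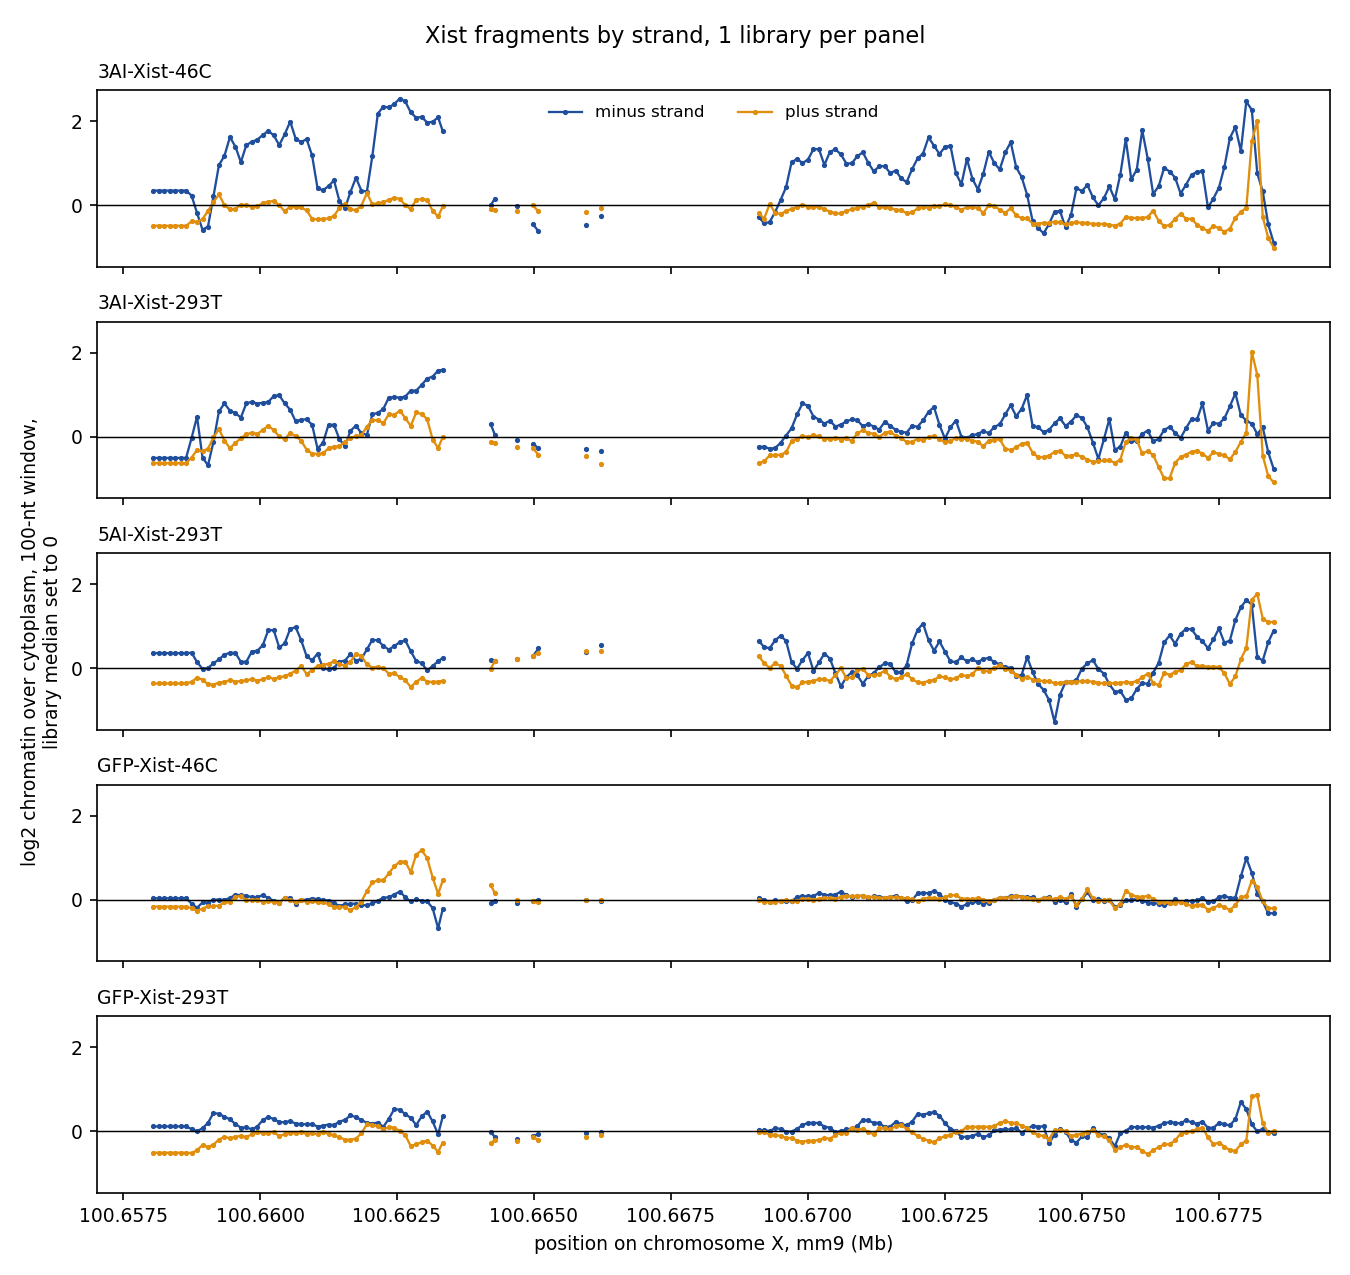
Each panel is 1 Xist library, with position on chromosome X (mm9, Mb) on the x axis and log2 chromatin over cytoplasm per 100-nt window on the y axis; points are windows and lines join adjacent windows of the minus (blue) and plus (orange) strand. In 3AI-Xist-46C the minus strand has a median of 0.80 and the plus strand of −0.13; the flat start is a run of equal deposited values.

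The 15 highest windows, 3 per library, fell in 2 stretches of chromosome X, 8 of them from 100677851 to 100678250 and 7 from 100662501 to 100663370. Both stretches pool the strands. In the stretch from 100662501, these windows were on the minus strand in the 3AI libraries and on the plus strand in GFP-Xist-46C. In the first stretch, 100678051 to 100678150 on the plus strand was on the chromatin side in every library, from 0.45 to 2.02, and so was the next window, 100678151 to 100678250, from 0.30 to 2.00. On the minus strand 100677951 to 100678050 ranged from 0.38 to 2.47. In the libraries 5AI-Xist-293T and GFP-Xist-293T the plus-strand window from 100678151 was the highest of all, at 1.77 and 0.85. In 3AI-Xist-293T the highest was that from 100678051, at 2.02, followed by 100663301 to 100663370 (1.59) and 100663201 to 100663300 (1.58) on the minus strand. In 3AI-Xist-46C the highest was 100662501 to 100662600 on the minus strand (2.54, 5.83-fold), and in GFP-Xist-46C it was 100662901 to 100663000 on the plus strand (1.17). The lowest windows were 100674451 to 100674550 on the minus strand in 5AI-Xist-293T (−1.28), and 100678451 to 100678550 on the plus strand in 3AI-Xist-46C (−1.01) and 3AI-Xist-293T (−1.09). In GFP-Xist-46C the lowest was 100663201 to 100663300 on the minus strand (−0.69), and in GFP-Xist-293T 100676151 to 100676250 on the plus strand (−0.55). The former window was among the 3 highest of 3AI-Xist-293T (1.58), so the libraries disagreed there. No window was in the top 5% of every library. On the chromatin side of all 5 libraries stood 48 of 312 windows, 43 of them on the minus strand, against a mean of 27.9 when the profiles were rotated (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). On the cytoplasm side stood 34 windows, all on the plus strand, against 28.1 (permutation p = 0.198).

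The authors' deposited table has p-values per 10-nt bin for a test over the libraries. Of the plus-strand bins, 497 of 1561 had a value under 0.05 in the authors' deposited table, 450 of them with a mean ratio toward the cytoplasm. Of the minus-strand bins it was 456, of which 452 had a mean ratio toward chromatin. The values in the authors' deposited table end at 0.5, as those of a test in the observed direction would, so that about 10% of bins would fall under 0.05 by chance. How neighbouring bins depend on each other was not taken into account there.

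The width of the profiles differed between libraries. Of the Xist windows, 21.2% (95% exact binomial interval 16.8 to 26.1) lay at least 1 from the median in 3AI-Xist-46C, 3.53% in 3AI-Xist-293T and in 5AI-Xist-293T (1.77 to 6.22), 0.641% in GFP-Xist-46C and 0 of 312 in GFP-Xist-293T. Of the RTM windows it was 13.9% in 5AI-RTM-293T (11.7 to 16.4), 4.28% in 3AI-RTM-293T, 1.72% in GFP-RTM-46C and 0 of 872 in GFP-RTM-293T. The 5AI-RTM-short replicates 1 and 2 had 4.24% and 3.14%, over 236 and 478 windows. These intervals treat windows as independent, which neighbouring windows are not. In 3AI-Xist-46C 65 of the windows beyond 1 lay on the chromatin side and 1 on the cytoplasm side. With strand medians of 0.80 (minus) and −0.13 (plus), this share is not separate from the strand difference above. In 5AI-RTM-293T 48 lay on the chromatin side and 73 on the cytoplasm side.

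The RTM libraries cover 7 mouse regions on both strands, which are given by position because the files do not name them. In chromosome 19, the plus strand from 8841161 to 8841260 and from 8841261 to 8841310 was in the top 5% of all 4 full libraries, from 0.87 to 2.72 and from 0.94 to 2.84. Rotated profiles gave a mean of 0.057 such windows (permutation p = 0.002). These were the highest windows of 5AI-RTM-293T (2.84), 3AI-RTM-293T (2.00), GFP-RTM-46C (2.01) and GFP-RTM-293T (0.94). They adjoin at the end of their region and are not separate findings, and their count was not repeated without region ends. On the minus strand, 8841161 to 8841260 was among the 3 lowest windows of GFP-RTM-293T (−0.79). In replicate 1 of 5AI-RTM-short the highest window was in the same region, 8840961 to 8841060 (2.38). In replicate 2 it was chromosome 7, 3217852 to 3217951, plus strand (2.77). The lowest windows were chromosome 1, 88243951 to 88244010, plus strand in 5AI-RTM-293T (−2.10), chromosome 19, 8839561 to 8839660, plus strand in 3AI-RTM-293T (−1.63) and GFP-RTM-293T (−0.83), and chromosome 19, 5802131 to 5802230, plus strand in GFP-RTM-46C (−1.51). They were 5798531 to 5798630 (−0.50) and 5829711 to 5829810 (−1.16), both on chromosome 19, plus strand, in replicates 1 and 2 of 5AI-RTM-short.

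In 9 of the 14 RTM regions by strand, the median farthest from 0 was that of 5AI-RTM-293T. The chromosome 5 region, 143665381 to 143668400, had medians of 0.99 on the plus and 0.82 on the minus strand there, 0.55 and 0.15 in 3AI-RTM-293T, 0.12 and 0.23 in GFP-RTM-46C, and 0.03 and −0.01 in GFP-RTM-293T. The chromosome 1 region, 88241311 to 88255930, had −0.56 and −0.51 in 5AI-RTM-293T, 0.00397 and 0.02 in 3AI-RTM-293T, −0.26 and −0.22 in GFP-RTM-46C, and −0.00191 and 0.03 in GFP-RTM-293T. On chromosome 19, the region from 8839461 to 8841310 had 0.88 and 0.32, 0.07 and −0.30, 0.40 and 0.21, and −0.08 and −0.37 in the same order of libraries. The region from 5795731 to 5802660 had −0.47 and 0.13, −0.10 and 0.14, −0.13 and −0.15, and 0.01 and 0.06. The region from 5824711 to 5845470 had −0.16 and 0.34, −0.06 and −0.01, 0.04 and 0.10, and −0.04 and 0.02. The chromosome 6 region, 122657591 to 122664620, had 0.72 and 0.28, 0.16 and 0.37, 0.24 and 0.15, and 0.38 and 0.24, positive in each. The chromosome 7 region, 3217852 to 3220991, had 0.29 and 0.13, −0.05 and 0.05, 0.33 and 0.25, and −0.17 and −0.13. In replicate 1 of 5AI-RTM-short the medians of the chromosome 19 regions were −0.03 and 0.19 from 5795731, −0.10 and −0.00251 from 5824711, and 0.17 and −0.19 from 8839461. In replicate 2 they were 0.00386 and −0.02 from 5824711, 0.16 on the plus strand of chromosome 6, and 0.04 and 0.04 on chromosome 7.

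In the RTM libraries the strand differences, averaged over the windows of all regions with values, lay between −0.02 and 0.19. The minus strand was further to the chromatin side by 0.19 in 5AI-RTM-293T (adjusted permutation p = 0.0167), 0.12 in 3AI-RTM-293T (0.0101), 0.06 in GFP-RTM-46C (0.0412) and 0.06 in GFP-RTM-293T (0.0387). It was 0.19 in replicate 1 (0.153) and −0.02 in replicate 2 (0.734) of 5AI-RTM-short. The direction varied by region. In 5AI-RTM-293T the plus-strand median was higher on chromosome 19 from 8839461 (0.88 against 0.32) and on chromosomes 5, 6 and 7. The minus-strand median was higher on chromosome 1 and in the chromosome 19 regions from 5795731 and 5824711. With 2-kb blocks the adjusted p-values were 0.0609 in 5AI-RTM-293T, 0.0896 in GFP-RTM-46C and 0.0869 in GFP-RTM-293T. Over the 4 full libraries, 98 of 864 windows were on the chromatin side in every one, against a mean of 69.5 after rotation (permutation p = 0.004), and 104 on the cytoplasm side, against 64.9 (permutation p = 0.001, the smallest possible).

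The same construct was then compared between the human and mouse cells, across windows and with circular shifts within each region and strand (two-sided permutation p, Benjamini-Hochberg over 12 pairs of libraries). Windows are not independent replicates, and each pair is 1 library against 1. The 3AI-Xist profiles were alike in 293T and 46C, with Pearson's r = 0.788 and Spearman's rho = 0.790 (adjusted permutation p = 0.0004 and 0.0003, from raw values at 0.0001, the smallest these shifts can give). With each strand centred on its own median, r was 0.714. The GFP-Xist profiles had r = 0.169 (adjusted permutation p = 0.15) and rho = 0.259 (0.0003). The GFP-RTM profiles of the cell lines had r = −0.152 (0.096) and rho = −0.225 (0.002), and r passed the threshold without the extreme 2% of windows at each end (−0.212, 0.00672) or the region ends (−0.176, 0.0341).

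Constructs that carry the same fragments were compared within a cell line. For Xist in 293T cells, the GFP profile followed those of 3AI (r = 0.580, adjusted permutation p = 0.0006; rho = 0.530, 0.002) and 5AI (r = 0.598, 0.0004; rho = 0.578, 0.00467). The 3AI and 5AI profiles had r = 0.323 (0.096) and rho = 0.305 (0.327). In 46C cells GFP and 3AI had r = 0.167 (0.0643) and rho = 0.306 (0.0003). With 50-nt windows (0.179, adjusted permutation p = 0.03) or strands centred (0.285, 0.0003), r there passed the threshold. For RTM in 293T cells, GFP and 3AI had r = 0.338 (0.0004) and rho = 0.284 (0.0003), and 3AI and 5AI r = 0.168 (0.00456) and rho = 0.182 (0.00285), with r = 0.130 (0.0566) in 200-nt windows. GFP and 5AI had r = 0.0215 (0.674) and rho = −0.0298 (0.565). In 46C cells GFP and the mean of the short pair had r = −0.0265 (0.641) and rho = −0.159 (0.00206), with r = −0.168 (0.0057) without the extreme 2% of windows at each end. Of these 652 windows, 591 hold the value of only 1 replicate. Replicate 2 alone gave rho = −0.194 (permutation p = 0.0005, unadjusted) and replicate 1 alone −0.0519 (0.713).

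**Figure D3:**
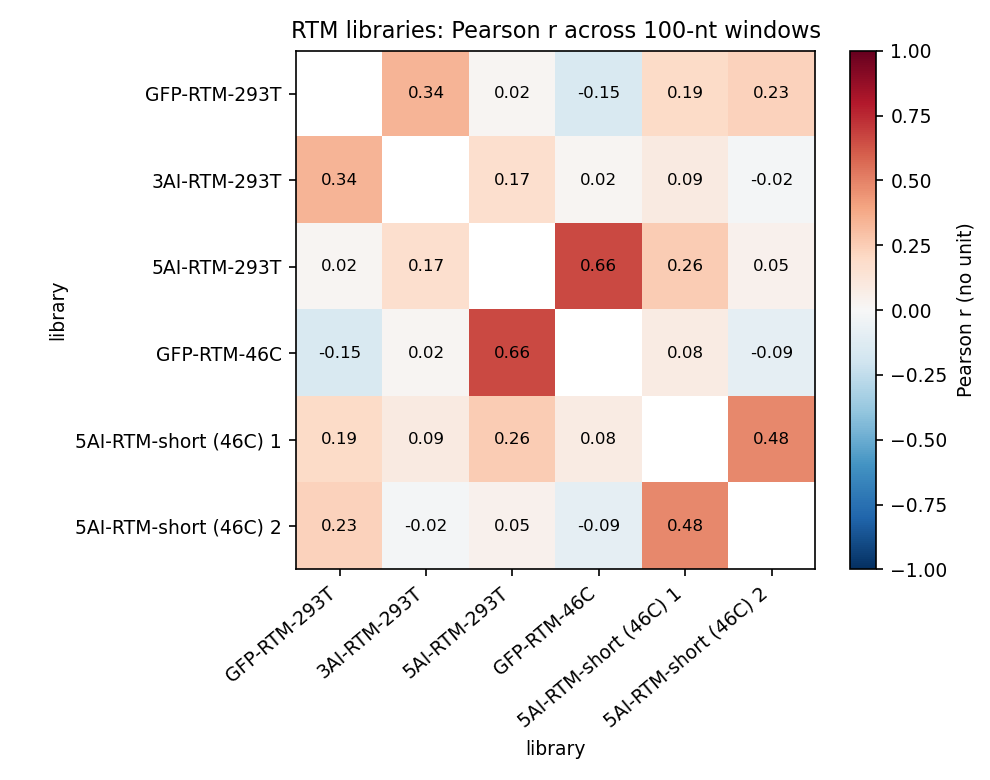
Pearson's r across 100-nt windows for each pair of RTM libraries (rows and columns are libraries, color and number are r). The pair 5AI-RTM-293T and GFP-RTM-46C stands at 0.66, above 0.48 for the 5AI-RTM-short pair and 0.34 for GFP and 3AI in 293T.

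The 5AI-RTM-short pair is the only group with more than 1 library. Nothing in the sources used here says whether these are replicates of 1 set of fragments, separate cultures or different sets of fragments. The libraries cover largely different regions, with values in 236 windows for replicate 1 and 478 for replicate 2. They shared 61 windows, all in the chromosome 19 region from 5824711, with r = 0.481 (adjusted permutation p = 0.0412) and rho = 0.171 (0.453). Without the extreme 2% of windows at each end r was 0.407 (0.12), with 50-nt windows 0.424 (0.063) and with 200-nt windows 0.467 (0.121). The SD of their difference per window was 0.34. Set beside it, the SD of the difference between constructs was 0.72 for GFP and 5AI, 0.74 for 3AI and 5AI and 0.41 for GFP and 3AI in the RTM libraries of 293T cells, and 0.55 for GFP and the short mean in 46C cells. In the Xist libraries it was 0.35 for GFP and 5AI, 0.39 for GFP and 3AI and 0.53 for 3AI and 5AI in 293T cells, and 0.76 for GFP and 3AI in 46C cells. In that last pair 3AI was higher by at least 1 in 61 windows and lower in 1. A spread taken from 1 pair over 61 windows of 1 region gives a scale, not a test. The SDs between RTM constructs also span differences between regions.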

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

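The values in this part were picked out because they ran in opposite directions in the 2 cell lines or because a test of the difference between cell lines passed its threshold; the strand tests were chosen after the data were seen. Each cell line has 1 library per construct, so library and cell line cannot be separated.

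The Xist strand difference was larger in 46C than in 293T cells with the 3AI construct, by 0.51 (adjusted block sign-flip permutation p = 0.00195, two-sided, over 3 comparisons). With the GFP construct it went the other way, and 46C minus 293T was −0.27 (adjusted permutation p = 0.00195). With 2-kb blocks both had an adjusted p of 0.0219. The corresponding value for GFP-RTM was −0.0026 (adjusted permutation p = 0.938). The GFP-Xist medians had opposite signs in the cell lines, with 46C minus 293T at 0.11 on the plus strand and −0.11 on the minus strand, which was not tested. The 46C medians were 0.00172 and −0.000955, which is 0 at the precision of the deposited ratios, against −0.10 and 0.11 in 293T.

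In the GFP-RTM libraries 9 of 14 region medians lay on opposite sides of 0 in the cell lines, and these differences were not tested. Because each library was centred on its own median, unrelated profiles would also give many opposite signs. The strands of a region are not independent either, so the count alone does not show a difference. Some of these signs rest on 293T medians near 0. Examples are −0.00985 on the minus strand of chromosome 5 and 0.00629 on the plus strand of chromosome 19 from 5795731. On chromosome 19 the region from 8839461 differed by 0.47 on the plus and 0.59 on the minus strand (46C minus 293T). The chromosome 7 region differed by 0.50 and 0.38, and the minus strand of the chromosome 5 region by 0.24. The minus strand of the chromosome 1 region differed by −0.25, the chromosome 19 region from 5795731 by −0.14 on the plus and −0.21 on the minus strand, and the plus strand of the region from 5824711 by 0.076.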

How the results depend on the processing

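Pseudocounts of 0.1 and 10 times, 50-nt and 200-nt windows and other choices were tried. The motif windows of RTM and Xist, the low-density filters and centring on totals were not run, since sequences and densities were not in the tables used. No paired analysis was possible because the groups share no replicate numbers in the labels. The alternatives that changed a call or moved a value past a set bound are given here. For region medians these were 5 of 385, with a bound set from the interquartile range of the windows. Smaller moves are left out, and some of them change the sign of a median. In 200-nt windows the minus strand from 5795731 in 5AI-RTM-293T went from 0.13 to −0.00568. The cause was not tested except where stated. The share of windows beyond 1 in 5AI-RTM-293T was 9.99% with a pseudocount 10 times as large and 11.5% in 200-nt windows, and in 3AI-RTM-293T 2.75% in 200-nt windows. The other 27 of 30 RTM values and all 25 Xist values stayed within their intervals. Without centring, medians of short replicate 1 on chromosome 19 moved to −0.14 (5795731, plus), −0.21 (5824711, plus) and −0.12 (5824711, minus), and that of the minus strand in GFP-Xist-46C to −0.06, since the subtracted library median was left in. The plus strand of chromosome 5 in 5AI-RTM-293T moved to 0.88 with 10 times the pseudocount. Among correlations, GFP with 3AI Xist in 46C cells passed the threshold with 50-nt windows (r = 0.179), without the extreme 2% (0.161) and with strands centred (0.285, added later). GFP-RTM between cell lines passed it without the ends (−0.176) and without the extreme 2% (−0.212), and GFP-RTM-46C with the short mean without the extreme 2% (−0.168). Leaving out a short replicate gave r from −0.0936 to 0.0801 and rho from −0.194 to −0.0519, which missed the threshold without replicate 2. The short pair missed it with 50-nt (0.424) and 200-nt windows (0.467) and without the extreme 2% (0.407), and 3AI with 5AI RTM in 200-nt windows (0.130). Strand differences that missed the threshold, all from alternatives added later, were those of 5AI-RTM-293T (0.19), GFP-RTM-46C (0.0587) and GFP-RTM-293T (0.0614) with 2-kb blocks, and of GFP-RTM-46C (0.0529) and GFP-RTM-293T (0.0629) in 200-nt windows; the other 55 of 60 did not change their call. For NXF1, 122 lower and 4 higher sites became 59 and 53 against the median site, and 8 and 1 beyond 3 robust SD of all sites. Against the median site the reference moved by −0.27, and an exact binomial test against a fixed ratio replaced Fisher's test. Among the sites named by the rule, site 59 turned to 0.18 against the median site. The splice site-like difference missed its threshold with GTAAG (−0.39) and with substitutions only (−0.41, added later). Ratios without counts leave the precision of single windows unknown.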

Other observations

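All tests of explanations in this part were chosen after the patterns were seen; those of flanking sites, of the step along the fragment, of strand and of region ends were stated before their own values were looked at.

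Of 480 NXF1 mutations tested, 18 were higher in chromatin than the unmutated row and 336 lower. The higher ones ran from site 16 to site 114, with 7 in the run of G from site 59 to site 64, where the second splice site-like stretch ends, and 11 elsewhere. Among those of the run, G60A stood at 0.41 ± 0.06, G61A at 0.22 ± 0.06, G61T at 0.25 ± 0.08, G64A at 0.22 ± 0.07 and G64C at 0.31 ± 0.19. Elsewhere, T16C stood at 0.34 ± 0.27, G51C at 0.39 ± 0.19 and T114del at 0.20 ± 0.10. Site 62, in the same run, was lower (−0.38 ± 0.05). These were chosen after their values were seen.

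The lower chromatin share of mutations in both 5′ splice site-like stretches was weighed against 4 explanations. Deletions placed by alignment in base runs do not account for the difference over both stretches, since with substitutions only they still lay below the other sites by −0.40 in median (circular-shift permutation p = 0.0069, the smallest possible). The bounds of this test were set after its value was seen, and for the fixed list alone substitutions gave a permutation p of 0.0552. Place in the fragment does not either, since the stretches lay below the 24 flanking sites by −0.56 in median. That closeness to the U1 consensus sets the chromatin share is a hypothesis that stays open. Of the 3 substitutions to the consensus base, 2 were higher than the others at their site, and G60T was lower than those at its own. Against the unmutated row G42A (0.15 ± 0.08) and G60T (0.17 ± 0.07) were higher and A52C (−0.15 ± 0.11) was lower. Splicing out of molecules with an intact site could also give the lower chromatin share, and cannot be told apart here. Mutated reads of the stretches lay above other sites in cytoplasm over whole cell, by 0.17, as either would have it.

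Sites named with a minus sign, from site 71 on, lay lower than those named with a plus sign, −0.33 against −0.13 in median outside the matches. The sources used here do not say what the sign means. A straight line is a weaker account, since it left 1.22 times the residual sum of squares of a step at site 71. Other smooth changes along the fragment were not tried. Separate reading or preparation of the 2 parts may give such a step and stays open, because the jump there ranked 8 among 108 boundaries, with the largest before site 67. No biological explanation was tested.

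The profile of 5AI-RTM-293T resembled that of GFP-RTM-46C, with which it shares neither construct nor cell line, more than that of any other RTM library (r = 0.662 over 870 windows, circular-shift permutation p = 0.0001, the smallest possible). In 10 of 14 regions by strand r was above 0.5, and in 2 it was below 0. The resemblance does not rest on region ends, since r was 0.661 without them. A candidate explanation is a factor that does not depend on strand, such as one of library preparation: the mean of both strands correlated at 0.770 and the strand difference at 0.179. Whether the column is in truth a library from 46C cells cannot be told apart. Correlation with the 5AI-RTM-short libraries from these cells (0.257 and 0.0453) does not decide it, since GFP-RTM-46C, from the same cells, gave 0.0801 and −0.0936. From the other cells, GFP-RTM-293T gave 0.191 and 0.233, and 3AI-RTM-293T 0.0903 and −0.0212. These correlations thus do not sort the RTM libraries by cell line. They do not check the cell line of the GFP-RTM columns either, on which the GFP-RTM comparison between cell lines rests. A biological account stays untested.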
